A study of Mus musculus with 2 samples.

How the data were processed

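Polyadenylated RNA was sequenced from mouse ES cells, 1 library of wild-type and 1 of Fbxl10 T/T genotype. Per the labels' protocols, the cells were grown in serum and LIF on inactivated mouse embryonic fibroblasts, the feeder cells were removed before use by letting them attach to plastic, and libraries were made with an Illumina mRNA kit from DNase-treated RNA of high integrity. Per the submitters' processing notes, the genome build was mm9 and the tools were TopHat 1.4.1, HTSeq 0.5.3p9 and edgeR. Their roles, the gene annotation and the strand setting are not given in the sources used here.

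The deposited table gives, for each gene, a normalised signal per library and the authors' log2 ratio of wild type over T/T. The signal was found from its values to be gene read counts per 1000000 reads of an effective library size that differs from the sum of the column, so it is called normalised CPM here. The columns summed to 887645 in wild type and 1098136 in Fbxl10 T/T, and the latter is above 1000000, which plain CPM does not allow. All values (100%) were whole multiples of a single step per library, within 0.01 reads, so whole reads were recovered: 1 read was worth 0.0419 CPM in wild type and 0.0405 CPM in Fbxl10 T/T. The recovered reads numbered 21198574 and 27109446 in the listed genes, and the limit set by 3 reads was 0.126 and 0.122 CPM. The 10 most abundant genes took 4.76% of these reads in wild type and 8.72% in Fbxl10 T/T. The table listed 24706 rows for 13620 distinct genes, and the 11086 repeated rows were used once. A symbol was given for 12724 genes in the file, 13443 identifiers matched the symbols of GENCODE M21, and 98 genes had none. Every listed gene had at least 22 reads in wild type or 28 in Fbxl10 T/T, so genes below this in both libraries were not analysed here. No gene with a symbol of the mitochondrial genome was listed. Coordinates are those of the deposited table. The ratios recomputed from the signal differed by at most 0.0028 from the authors' log2 ratios over 9311 genes at 5 CPM or more in both libraries.

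The log2 ratio of a gene is log2 of (T/T CPM + 0.5) over (wild-type CPM + 0.5), so positive values are higher in Fbxl10 T/T. Folds are ratios of the CPM values without a pseudocount. Genes at 1 CPM or more in at least 1 library were counted as 2-fold higher, 2-fold lower or in between. With 1 library per genotype no test of the genotypes was possible. Exact binomial (Clopper-Pearson) 95% intervals of single-gene ratios were computed from the recovered reads; PCR copies are not independent molecules, so intervals and read limits cover counting error only. For those of the 29 gene lists with at least 5 measured genes, the median log2 ratio was given with an interval from its order statistics and its percentile among 10000 random lists of the same size, drawn in 20 bins of mean expression. The percentile describes these 2 libraries. Because of the unit, counts were tested only as an added comparison of the libraries: an exact two-sided binomial test with Benjamini-Hochberg adjustment called 5780 genes higher and 5564 lower at an adjusted p of at most 0.05, and edgeR 4.0.16 was run on the recovered reads with an assumed biological coefficient of variation of 0.2. Both compare the libraries, not the genotypes.

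The size rule, the gene lists and the rule for named genes were fixed before the data were examined. The named genes are Kdm2b, the 12 largest and 12 smallest log2 ratios among genes with a symbol and at least 5 CPM in 1 library, up to 2 members at either end of each list, and all members of lists with up to 4 members. Some genes that this rule names are not reported here. Names could be left out for lists whose median lay between the 5th and 95th percentile. Further lists (parietal endoderm, visceral endoderm, collagen modification and export; 3 in all) were written after the data were seen, without genes whose values had been looked at. Alternatives were pseudocounts of 0.1 and 1 CPM, no minimum or a minimum of 5 CPM, rescaling to a common median or upper quartile, fold thresholds of 1.5 and 4, and the added tests. Classes of promoters by CpG content were planned and not analysed here, as no genome sequence was used. The steps were tested on simulated reads of 13620 genes for the comparison of Fbxl10 T/T with wild type: 100% of 100 genes changed 4-fold and of 100 changed 8-fold passed the 2-fold rule, as did 1 of 12906 unchanged genes, and 95.5% of intervals covered the true ratio. The simulated reads held counting error only, without variation between cultures or library preparations, so these shares do not measure errors from such variation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.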

Results

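Gene expression was measured by sequencing polyadenylated RNA from mouse embryonic stem (ES) cells of the C57BL/6J strain, with 1 library from wild-type cells and 1 from cells of genotype Fbxl10 T/T. Fbxl10 is an older symbol of Kdm2b. Its protein is a subunit of the variant Polycomb complex PRC1.1 and has a CXXC domain that binds unmethylated CpG islands. The series concerns the role of this protein at genes bound by Polycomb, and the comparison asks how RNA levels in cells homozygous for the T allele differ from those in wild-type cells. The table listed 13620 genes, with 21198574 reads in the wild-type library and 27109446 in the Fbxl10 T/T library, and 13512 genes reached 1 CPM (normalised read counts, scaled to library size) in at least 1 library. The most abundant RNA was Hsp90ab1 in wild type, with 152298 reads, and the collagen IV gene Col4a1 in Fbxl10 T/T, with 455355 reads. There were no replicates, so no difference between the genotypes was tested, and "higher" or "lower" below describes these 2 libraries. Intervals for single genes are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only.

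Kdm2b itself was 9.66-fold lower in the Fbxl10 T/T library, at 10.6 CPM against 102.5 CPM in wild type, with a counting interval of 8.50- to 11.02-fold. The gene (ENSMUSG00000029475, listed under its older symbol) lies on chromosome 5 from 123320688 to 123439832 in mm9. It kept 10.3% of its wild-type level (95% counting interval 9.08 to 11.8%), from 262 reads. The authors' deposited table gives a log2 ratio of 3.27 for wild type over T/T. The labels do not say which part of the gene the T allele alters, so the gene-level value may include reads from an unaltered part.

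Pluripotency genes were lower and endoderm genes higher in the Fbxl10 T/T library, and genes of most other lineages were lower. Of the 13512 genes, 1994 (14.8%) were at least 2-fold higher, 2781 (20.6%) at least 2-fold lower and 8737 (64.7%) in between, on the log2(CPM + 0.5) scale, which understates the ratios of low genes. At a 4-fold threshold 519 genes were higher and 1229 lower. With the values rescaled to the upper quartile the split at 2-fold was 1435 higher and 3254 lower, and with a minimum of 5 CPM it was 1828 higher and 1737 lower. Across genes, which are not independent replicates, Pearson's r between the libraries was 0.87 and Spearman's rho was 0.88.

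**Figure D1:**
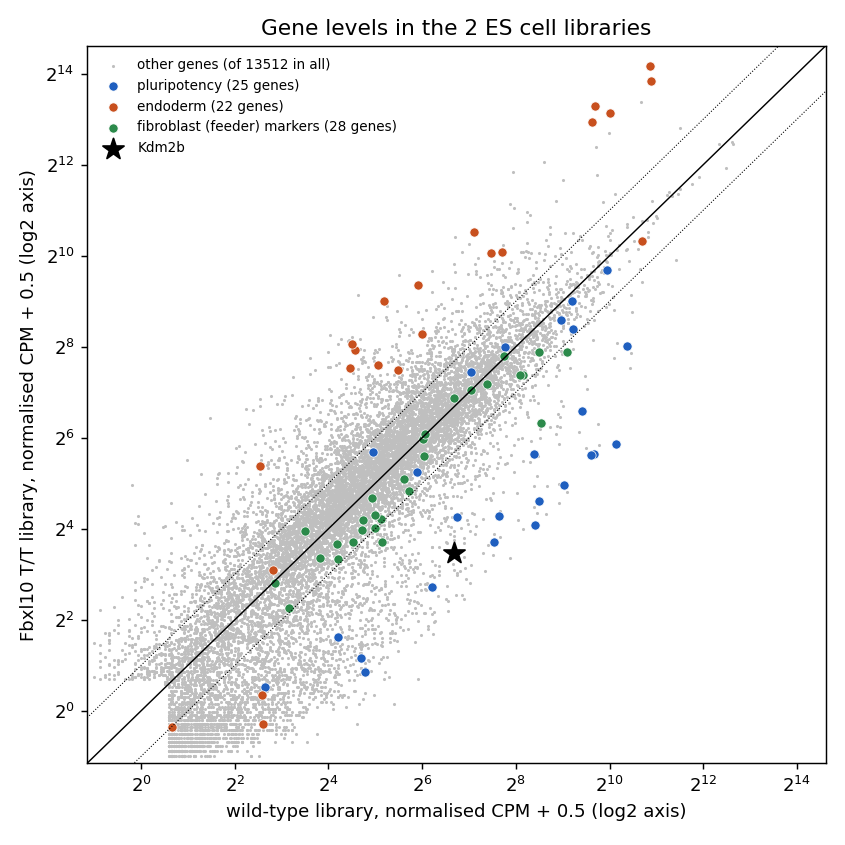
Each point is 1 of the 13512 genes at 1 CPM or more in at least 1 library, with its wild-type level on the x axis and its Fbxl10 T/T level on the y axis (normalised CPM + 0.5, log2 axes; solid line, equal levels; dotted lines, 2-fold). Of the coloured lists, 17 of 25 pluripotency genes lie below and 17 of 22 endoderm genes above the 2-fold lines, while 25 of 28 fibroblast markers lie between them. Kdm2b is at 102.5 and 10.6 CPM.

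Of the 25 pluripotency genes measured, 17 were at least 2-fold lower, none was 2-fold higher and 8 lay in between. The median log2 ratio was -2.73 (95% interval of the median -3.84 to -0.82), below all 10000 random lists matched on expression. The smallest ratios on the log2(CPM + 0.5) scale were those of Nr0b1, a nuclear receptor gene, at 339.8 against 16.4 CPM (20.7-fold lower), and Tdgf1, a Nodal co-receptor gene, at 1128 against 58.0 CPM (19.4-fold lower). Nanog, Sox2 and Pou5f1, which encode core pluripotency factors and were picked after their values were seen, were 16.0-, 16.8- and 5.18-fold lower. Klf5 (132.2 and 173.6 CPM) and Fbxo15 (30.6 and 51.0 CPM) were slightly above their wild-type levels. Of the 9 primed epiblast genes measured, 7 were lower and none higher (median -1.48, interval -3.59 to -0.15, percentile 0.5). Foxd3 was 22.7-fold and Sox3 18.8-fold lower, while Otx2 was at 11.3 and 10.1 CPM and Dnmt3b at 213.3 and 283.7 CPM.

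Of 22 endoderm genes, 17 were higher, 3 lower and 2 in between. Their median log2 ratio was 2.90 (interval 1.99 to 3.35), above all 10000 random lists. Sox17, a transcription factor gene of endoderm, went from 35.8 CPM in wild type to 514.7 CPM in Fbxl10 T/T (14.4-fold), and Lama1, which encodes a basement membrane laminin chain, from 823.3 to 10036 CPM (12.2-fold). Gata4 and Gata6, picked after their values were seen and encoding primitive endoderm factors, were 10.8- and 10.9-fold higher, and the basement membrane genes Col4a1, Lamb1 and Sparc were 9.91-, 9.92- and 7.77-fold higher. Sox17 and Foxa2 (267.1 against 22.2 CPM, picked after its value was seen) are expressed in definitive as well as extraembryonic endoderm. Foxa1 and Cxcr4, also used as markers of definitive endoderm, were lower, at 5.57 against 0.324 CPM and 5.44 against 0.770 CPM. Fibroblast markers, which would mark RNA from the feeder cells, had a median log2 ratio of -0.59 (interval -0.81 to -0.26), with 0 of 28 genes higher and 3 lower. This median lay below all 10000 random lists matched on expression, whose typical median was 0.14, so the markers were modestly lower as a group. Col1a1 was at 101.6 and 117.3 CPM and Postn at 10.8 and 14.9 CPM, while Fstl1 was 4.68-fold and Loxl1 2.77-fold lower.

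**Figure D2:**
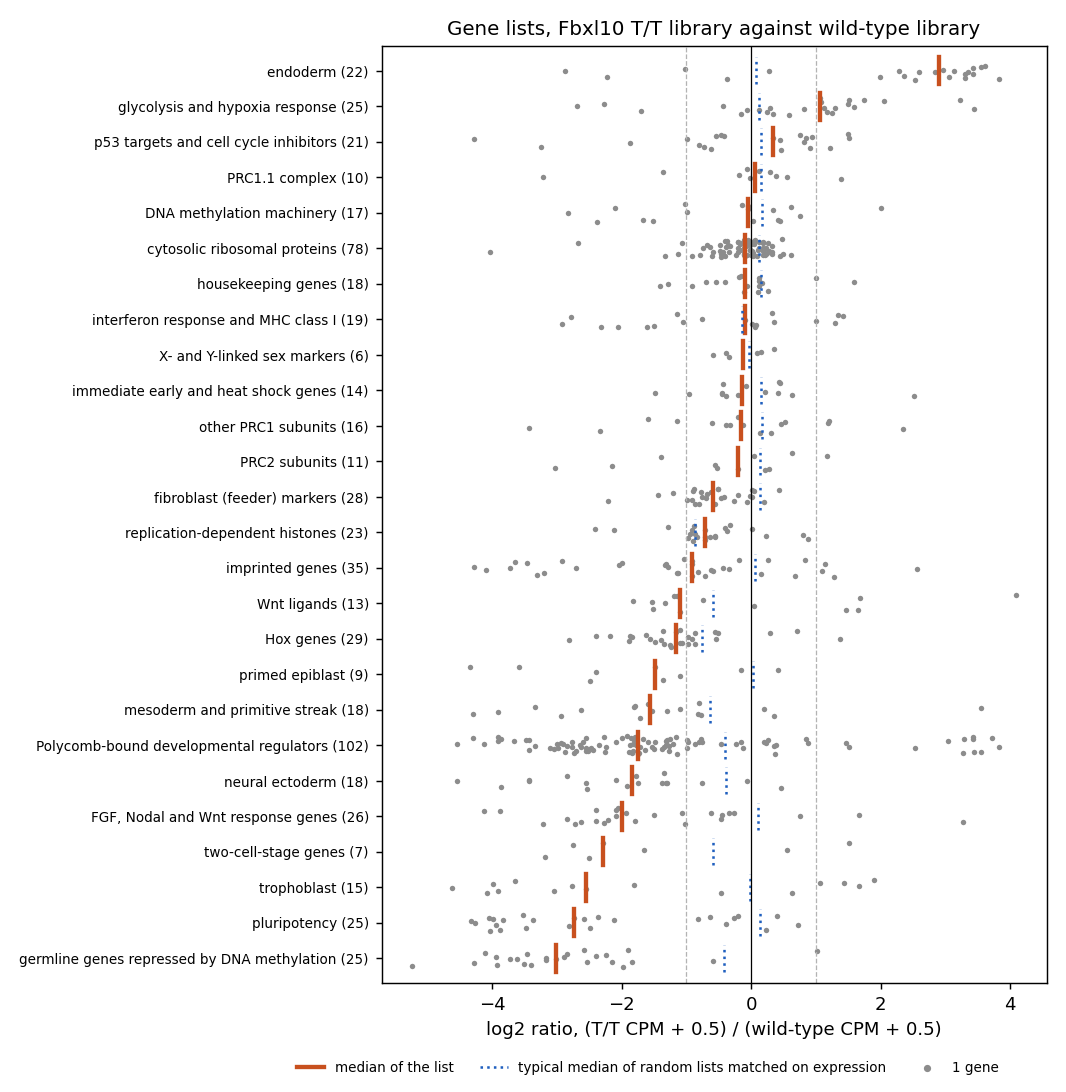
Each grey point is the log2 ratio of 1 gene, (T/T CPM + 0.5) over (wild-type CPM + 0.5); lists with at least 5 measured genes are ordered by their median (orange), with the number of genes in brackets. Blue dotted marks give the typical median of random lists matched on expression. The endoderm median lies at 2.90 and the germline gene median at -3.01.

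The genes of other lineages were mostly lower in Fbxl10 T/T. Among 18 neural ectoderm genes 15 were lower and none higher (median -1.85, interval -2.84 to -1.32, below all random lists). En2, a homeobox gene of midbrain and hindbrain, was 32.8-fold lower and Olig1 16.3-fold lower, while Nes was at 26.5 and 25.4 CPM and Tubb3 at 59.9 and 82.2 CPM. Among 18 mesoderm and primitive streak genes 12 were lower and 1 higher (median -1.56, interval -2.63 to -0.80, percentile 0.82). Bmp4 was 23.3-fold and Hand1 24.8-fold lower. Kdr, which encodes a VEGF receptor, was the higher gene, at 36.5 against 2.64 CPM. Trophoblast genes divided, with 9 of 15 lower and 4 higher (median -2.56, interval -3.92 to 1.07, below all random lists). Krt7 was 39.9-fold lower and Tfap2c went from 76.2 to 4.01 CPM, whereas Krt8, a simple epithelial keratin gene, was 3.74-fold and Plet1 3.19-fold higher.

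Developmental regulators known to be bound by Polycomb in ES cells were lower as a group. Of the 102 measured among 161 listed, 71 were lower, 12 higher and 19 in between. The median was -1.74 (interval -1.91 to -1.32), below all 10000 random lists, whose typical median was -0.40, and the fibroblast marker median was -0.59. On the log2(CPM + 0.5) scale, En2 and Bmp4 had the smallest ratios, and Fgf10 (105.9 against 7.54 CPM) and Sox17 the largest. Without members of the endoderm and pluripotency lists, a check added after the data were seen, 70 of 95 genes were lower and 7 higher, with a median of -1.79. That check kept the 16 genes shared with the neural ectoderm list and the 13 shared with the mesoderm and primitive streak list. The lower medians of these lists are therefore not separate results. The summed level of the 95 genes was 840.2 CPM in wild type and 624.6 CPM in Fbxl10 T/T, a ratio of 1.35. The median depended on the pseudocount, from -2.44 with 0.1 CPM to -1.32 with 1 CPM. Of 29 Hox genes 18 were lower and 1, Hoxb4, was higher (median -1.16), at percentile 10.8 of random lists. Of 13 genes for Wnt ligands 7 were lower and 4 higher (median -1.09, percentile 11.6). Wnt4 was 18.0-fold higher, at 160.7 against 8.92 CPM, and Wnt7b 3.27-fold higher. With only members at 5 CPM or more the Wnt median turned to 1.56.

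Germline genes that are silenced by DNA methylation in somatic cells were lower in Fbxl10 T/T. Of 25 measured, 23 were lower, 1 higher and 1 in between (median -3.01, interval -3.52 to -2.40, below all random lists). Stra8, which acts at meiotic entry, was 68.2-fold lower, at 0.608 against 41.5 CPM, and Taf7l 35.9-fold lower. Random lists matched on expression had a typical median of -0.42 for this list. Brdt was the higher gene, at 3.65 against 1.55 CPM, and Tdrkh was at 1.05 and 0.527 CPM. All 3 measured genes of the X-linked Rhox homeobox cluster were lower: Rhox6 went from 24.0 to 0.324 CPM, Rhox9 from 13.02 to 0.203 CPM and Rhox1 from 2.01 to 0.0810 CPM. Of 7 genes of the 2-cell stage 5 were lower and 1 higher (median -2.29, interval -3.18 to 1.51, percentile 0.04). Tmem92 was at 4.77 and 0.0810 CPM, Usp17lc at 3.14 and 0.0405 CPM, Eif1a at 77.2 and 114.2 CPM and Zfp560 at 1.93 and 6.40 CPM. Of 35 imprinted genes 17 were lower, 4 higher and 14 in between (median -0.91, interval -1.33 to -0.60, below all random lists). Cdkn1c, a cell cycle inhibitor gene, was 22.2-fold lower and Slc38a4, an amino acid transporter gene, 17.8-fold lower. Airn, the antisense RNA at Igf2r, was higher at 4.90 against 0.419 CPM, and Peg3 was 2.44-fold higher. The interval listed for Airn, 13009250 to 13011409 on chromosome 17 in mm9, lies outside that listed for Igf2r, which ends at 12962530.

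Subunits of the Polycomb complexes and the DNA methylation machinery did not move in a single direction. Of the 10 PRC1.1 genes, Kdm2b and Bcor (2.60-fold) were lower, Yaf2 was 2.66-fold higher and 7 lay in between, with a median of 0.06 that turned negative when the libraries were rescaled to a common median. Of 16 other PRC1 genes 4 were lower and 3 higher (median -0.16). Phc1 went from 861.2 to 79.0 CPM (10.9-fold lower) and Cbx7 from 368.0 to 72.5 CPM, while Pcgf5 was 5.20-fold and Phc2 2.31-fold higher. Among 11 PRC2 genes 3 were lower and 1 higher (median -0.20). Phf19 and Jarid2 were 11.5- and 4.46-fold lower and Phf1 was 2.29-fold higher. The core genes Ezh2 (51.0 and 62.1 CPM) and Suz12 (41.2 and 42.7 CPM), picked after their values were seen, were within 1.5-fold of wild type. Of 17 DNA methylation genes 6 were lower and 1 higher (median -0.06). The dioxygenase genes divided: Tet1 was 7.28-fold and Tet2 5.66-fold lower, and Tet3 4.10-fold higher.

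**Figure D3:**
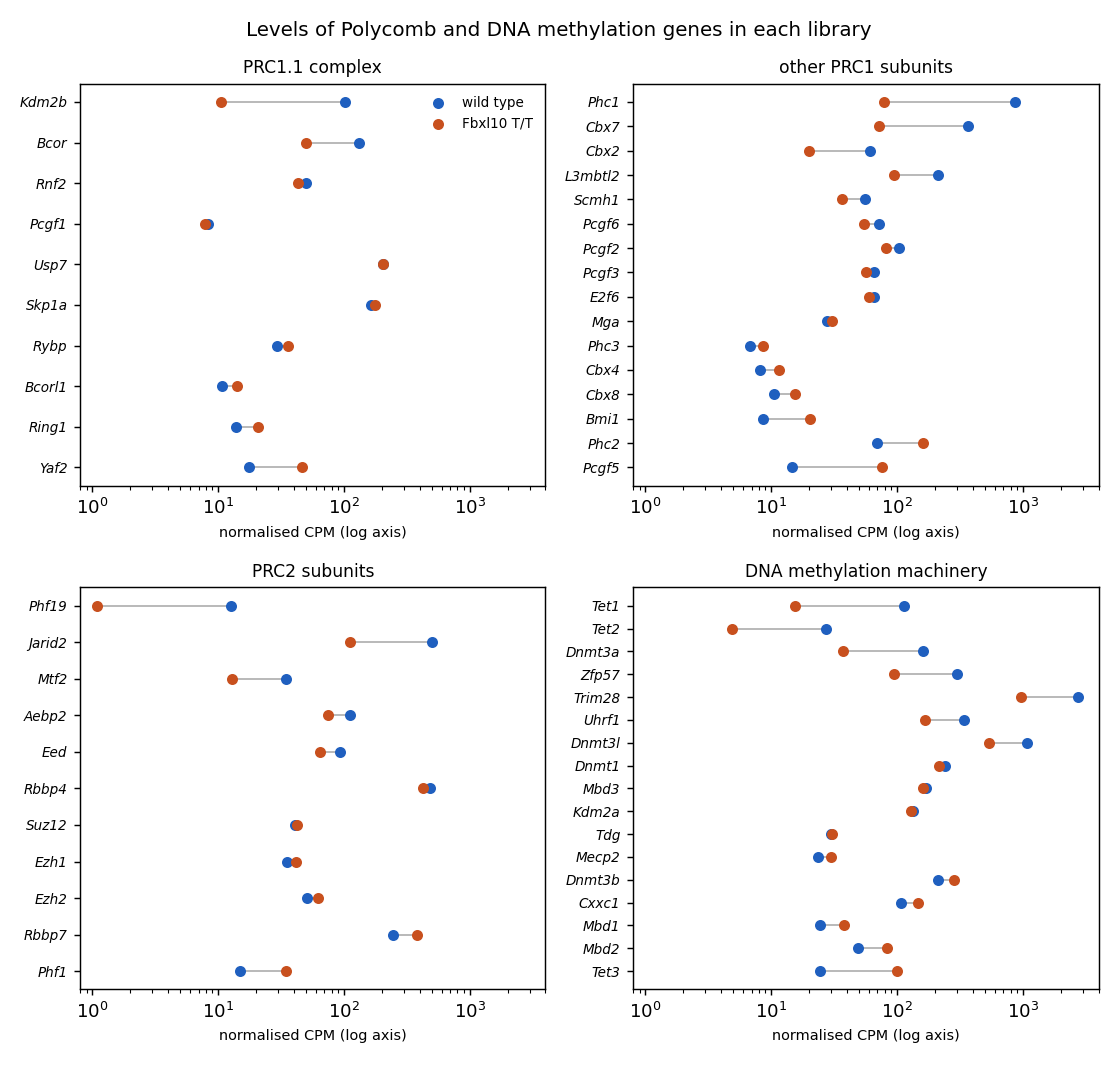
Points give the level of each gene in the wild-type library (blue) and the Fbxl10 T/T library (orange) in normalised CPM on a log axis, with 1 row per gene and the lowest T/T to wild-type ratio at the top of each panel. Tet1 lies to the left of wild type in Fbxl10 T/T (15.6 against 113.6 CPM) and Tet3 to the right (100.3 against 24.5 CPM).

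Genes that respond to FGF, Nodal and Wnt signals were lower in 18 of 26 cases and higher in 2 (median -2.0, interval -2.39 to -0.62, below all random lists). Cdx1 was 27.2-fold and Fgf4 15.0-fold lower, whereas Dusp4 was 3.19-fold higher. Glycolysis and hypoxia genes were higher in 13 of 25 cases and lower in 3 (median 1.06, interval 0.25 to 1.29), and 1 of 10000 random lists lay as high. The collagen prolyl hydroxylase genes P4ha1 (811.7 against 73.9 CPM) and P4ha2 (9.39-fold higher) led this list, while Pfkm and Pdk1 were 6.76- and 4.93-fold lower. Cell cycle inhibitors and p53 targets had a median of 0.34, with 3 of 21 higher and 3 lower, at percentile 82.6. The medians of immediate early and heat shock genes (-0.14, 14 genes) and interferon and MHC class I genes (-0.10, 19 genes) were at percentiles 9.51 and 55.8.

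Housekeeping genes were at similar levels, with a median of -0.09 over 18 genes. Gusb and Polr2a were more than 2-fold lower and Pgk1 was 3.04-fold higher, while Tubb5 and Eef1a1 were less than 1.1-fold from wild type, in a direction that flipped when the libraries were rescaled to a common median. Gapdh (28.6 and 25.4 CPM), Ppia (15.2 and 9.15 CPM) and Pgk1 share sequence with processed pseudogenes, so their levels are uncertain. The median of 78 cytosolic ribosomal protein genes was -0.09 (percentile 1.1), with 5 lower and none higher. Of these, Rpl10l, a paralogue of the more widely expressed Rpl10, was 22.1-fold lower, and Rpl3l was at 3.48 and 0.122 CPM. Rpl32 and Rps27l were 1.41- and 1.53-fold above wild type. Levels on this list were very uneven, with Rpl23a at 2.18 and 1.09 CPM, Rps6 at 12.4 and 7.01 CPM and Rpl8 at 2820 and 2610 CPM. Loss of reads to processed pseudogenes was not tested for this list, so its median and percentile are uncertain. Replication-dependent histone genes had a median of -0.71 over 23 genes (percentile 68.5). Of 4 clustered protocadherin entries, that of the alpha cluster, which joins several isoforms, was at 1.80 and 0.365 CPM, that of the gamma cluster, likewise joined, at 169.0 and 140.4 CPM, Pcdhb17 at 1.47 and 0.851 CPM and Pcdhb22 at 0.712 and 1.26 CPM. The Y-linked genes Uty (1.88 and 1.09 CPM), Eif2s3y (12.2 and 9.20 CPM) and Ddx3y (4.90 and 5.27 CPM) were detected in both libraries, and none of the 6 sex-linked markers differed 2-fold. Chromosome medians lay between -0.14 (chromosome 17) and 0.22 (chromosome 6) over the autosomes and X, with 0.01 on X. Though small, some were extreme among random gene sets matched on expression. Chromosomes 17 and 7 (-0.11) lay at percentiles 0 and 0.02. Chromosomes 6 and 13 (0.19) both lay at percentile 100. The cause was not tested.

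The genes at the ends of the range were ranked on the log2(CPM + 0.5) scale among genes at 5 CPM or more in at least 1 library. Vnn1, a pantetheinase gene, was 38.2-fold higher, at 86.4 against 2.26 CPM, and Adamts9, a secreted metalloprotease gene, was at 559.2 against 24.3 CPM. The potassium channel gene Kcnk13 (30.8-fold), the ephrin gene Efna1 (21.7-fold), the cytokine gene Il33 (20.6-fold), Gcnt1 (19.6-fold) and Flrt3 (19.3-fold) were also higher, as were Tfec, Krt23, Serpinb6b and Btn1a1. Krt23, Serpinb6b and Btn1a1 had 11, 10 and 11 reads in wild type. The processed pseudogene Rplp0-ps1 had the largest log2 ratio, at 30.5 against 0.377 CPM, but its reads can be shared with its parent Rplp0 (1806 and 1365 CPM) and it overlaps Flg, so its value is uncertain. At the other end, the ATP-gated channel gene P2rx7 was 40.3-fold lower, at 0.608 against 24.5 CPM. P2rx7 lies near Kdm2b, on chromosome 5 from 123093920 to 123141441 in mm9, and an effect of the altered locus on it was not tested. Gpa33, a surface antigen gene, was 24.0-fold lower at 9.80 against 235.1 CPM, and the glycosyltransferase gene Galnt6 23.6-fold lower at 5.02 against 118.5 CPM. Sox15, Zfhx2, Arl14epl and 8030474K03Rik were 33.1-, 31.6-, 27.4- and 37.9-fold lower. Genes at 1 CPM or more in 1 library and below 0.1 CPM in the other numbered 190 for wild type and 12 for Fbxl10 T/T, and 1 and 0 of these, respectively, reached 5 CPM.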

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

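No paired analysis was possible because there was 1 library per genotype, and for the same reason no library could be left out. The promoter CpG classes were not run. Rescaling to a common median or upper quartile divided the Fbxl10 T/T values by a factor of 0.13 or 0.24 on the log2 scale, which moves the ratios of low genes less because of the pseudocount, and the 2-fold split of 1994 higher and 2781 lower genes became 1675 and 3011, or 1435 and 3254. Higher genes numbered 3582 at a 1.5-fold and 519 at a 4-fold threshold. Lower genes numbered 1229 at 4-fold and 1737 with a minimum of 5 CPM, which tests fewer genes and leaves more higher (1828) than lower genes. Adding the binomial test left both counts at 1994 and 2781. The edgeR calls used neither the 2-fold rule nor the 1 CPM minimum and depended on the assumed variation, so their counts are not set beside these. The neural ectoderm median moved to -3.06 with a pseudocount of 0.1 CPM and -3.14 with a minimum of 5 CPM, the Polycomb-bound regulator median to -2.44 and -1.32 with pseudocounts of 0.1 and 1 CPM, the germline median to -3.87 with 0.1 CPM and -3.56 with a minimum of 5 CPM, the 2-cell-stage median to -3.32 and the histone median to -0.96 with 0.1 CPM, and the ribosomal protein median to -0.21 after median rescaling. A pseudocount shrinks the ratios of low genes by construction. The Wnt ligand median reversed to 1.56 with a minimum of 5 CPM, since fewer genes remained. The other 126 list medians under an alternative stayed within their intervals. Some medians near 0 changed sign within them: p53 targets became -0.04, interferon genes 0.06 and sex markers 0.09 with a minimum of 5 CPM, and PRC1.1 genes -0.07 after median rescaling. Of the genes detected in 1 library, 38 (wild type) and 2 (Fbxl10 T/T) remained when the other library had to be at exactly 0, 1 and 0 with a minimum of 5 CPM, and 140 and 9 with a minimum of 1.2 CPM, a setting chosen after seeing the data because the lowest listed level was 0.921 CPM in wild type and 1.13 CPM in Fbxl10 T/T. Pearson's r across genes became 0.878 with a pseudocount of 1 CPM. The largest chromosome median, that of chromosome 6, was 0.43 with a minimum of 5 CPM, and 32 of 100 single chromosome medians recomputed under an alternative left their interval, by median rescaling or that minimum. For the other moves the cause was not tested. The Kdm2b ratio stayed within its counting interval in the 3 alternatives run for it. Without a pseudocount, the upper-quartile factor of 1.18 would take its 9.66-fold difference past the upper limit of 11.02-fold. Depth set the lower limit of the measurement, 3 reads being worth 0.126 CPM in wild type and 0.122 CPM in Fbxl10 T/T.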

Other observations

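The tests of the parietal, visceral and collagen lists below were set before their values were seen; all others were chosen after the result. Genes for the modification and export of collagen, a list written after the basement membrane genes had been seen, were higher in Fbxl10 T/T in 18 of 21 cases and lower in 2. Their median log2 ratio was 2.03 (interval 1.45 to 2.43), at percentile 100 of random lists matched on expression. This met the preset criterion of lying above the 95th percentile. With 1 library per genotype, it does not show that these genes change together with Col4a1 and Lama1. Plod2, a lysyl hydroxylase gene, went from 49.5 to 476.2 CPM, P3h2, a prolyl hydroxylase gene, from 6.24 to 70.0 CPM and Creb3l2 from 37.7 to 387.1 CPM, while Fkbp10 was 3.31-fold lower.

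Genes of parietal endoderm other than those already named were higher in 8 of 16 cases and lower in 3 (median 0.88, interval -0.73 to 2.99, percentile 99.6), and genes of visceral endoderm higher in 5 of 14 and lower in 6 (median 0.14, interval -1.70 to 2.08, percentile 82.0, turning negative when the libraries are rescaled to a common upper quartile). Plat, the tissue plasminogen activator gene, went from 22.7 to 241.5 CPM and Pth1r from 43.3 to 439.5 CPM. Of the visceral genes, Lrp2 went from 246.8 to 2103 CPM and Dkk1 from 6.74 to 60.8 CPM, while Apoa2 was lower at 2.03 against 13.3 CPM and Cdh1, the E-cadherin gene, at 163.6 against 715.1 CPM. The hypothesis that the endoderm programme is parietal-like rather than visceral-like required medians more than 1 apart. They were 0.74 apart, so by the preset rule the result went against the hypothesis. A 95% bootstrap interval over genes, added after the result, ran from -1.19 to 3.66. It holds values on both sides of 1, so the difference is too uncertain to settle the question.

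The first pattern is the lower level of pluripotency genes with the higher level of endoderm genes. A single scaling factor per library moves both lists alike, and their medians lay 5.63 apart on the log2 scale, which argues against scaling. More feeder RNA in the Fbxl10 T/T library would raise the fibroblast markers, whose median was -0.59 and whose most abundant gene, Fbln2, was at 237.3 against 545.6 CPM. Feeder cells were also depleted before use. With 1 library per genotype, an effect of the allele and another difference between the 2 cultures, such as spontaneous differentiation towards primitive endoderm in a share of the cells, cannot be told apart.

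The second pattern is the 262 Kdm2b reads in the Fbxl10 T/T library. If they came from wild-type RNA carried into the library, no gene could lie below the share that Kdm2b kept, yet 110 of 6878 genes at 20 CPM or more in wild type did so beyond counting error. Reads from an unaltered part of the gene, or from feeder cells with the intact gene, remain open, because gene-level values do not separate them.

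The third pattern is the lower level of Polycomb-bound regulators and germline genes. Counting error at low read numbers is argued against: of all 95 measured regulators outside the endoderm and pluripotency lists, the counting interval lay below equal levels for 78, above for 12 and across for 5, and of all 25 germline genes below for 23. This test was chosen after a test on summed levels had come out the other way for the regulators, whose sum was only 1.35-fold lower (log2 ratio -0.43), while the germline sum was 16.4-fold lower. Across all 13620 listed genes, the added binomial test called 5564 lower and 5780 higher at an adjusted p of at most 0.05. Most genes thus lay beyond counting error, so the interval counts say little about these lists in particular. A loss of pluripotent cells alone may account for the pattern if these genes are silent in the cells that replaced them: only for 3 of 120 members (En2, Stra8 and Taf7l) did the upper 95% counting limit lie below the 4.78% of its wild-type level that Prdm14, the most reduced pluripotency gene, kept. The pluripotency genes did not fall alike, with 17 of 25 at least 2-fold lower and 8 in between. Among these 8, Dppa5a was at 817.3 against 984.9 CPM in wild type and Zfp42 at 37.4 against 58.5 CPM. Prdm14 alone therefore does not give the share of pluripotent cells lost. A loss of such cells and a direct effect at the regulators and germline genes cannot be told apart, because the level of Prdm14 in the other cells is not known.

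Weakly expressed genes as a whole were lower in Fbxl10 T/T. In 20 equal bins of mean expression the median log2 ratio was -1.22 in the lowest (0.502 to 1.09 CPM) and -0.49 in the fourth (2.64 to 3.98 CPM), and 0.21 in the tenth (18.5 to 23.2 CPM). In the lowest bin part of this follows from the listing limits of 0.921 CPM in wild type and 1.13 CPM in Fbxl10 T/T.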
